A study of Mus musculus with 48 samples.

How the data were processed

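Total RNA of epididymal white adipose tissue from 48 mice was measured on the NanoString nCounter Mouse Immunology panel. The deposited table holds counts: per its values, whole numbers of barcodes per probe, not scaled between samples. It has 547 endogenous genes, 14 reference genes, 8 negative control probes and 6 positive control probes. The lowest value is 1, found in 151 of the 27600 values, and the table does not show whether counts of 0 were set to 1. The tool and version the authors used to make the counts are not stated. Each column belonged to a sample, and groups were taken from the sample labels. The replicate numbers carried no pairing: libraries of different diets with the same number had a mean correlation of -0.016 over 112 pairs, and those with different numbers 0.0067 over 846. No 2 libraries were copies, with a lowest chi-square per degree of freedom of 6.03 over 1128 pairs. Probe identifiers were matched to a RefSeq table of the mouse genome for names only; 549 of 561 matched, and symbols are printed as in the table, though 13 are not current (Emr1 is now Adgre1).

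Counts were scaled to the geometric mean of the 14 reference genes. Genes with a mean count of at least 10 over all samples were tested, 491 of 547. All 48 samples were fitted together in edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with a mean per diet group. The p-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. The 13 comparisons were each fat-rich diet against chow, the carbohydrate and fat effects over the 4 custom diets, their interaction, the 4 pairwise steps, and the Western diet against sucrose/palmitate. An F test asked for any difference among the 6 groups. The 24 gene lists and the list of reference genes were tested with fry (limma 3.58.1), with adjustment over lists within a comparison. Comparisons, tests, lists and the first set of alternatives were fixed before the data were examined.

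Genes named in the text come from a rule fixed at the same time: the 8 highest and 8 lowest differences past the threshold, up to 3 members of each list that passed, 21 genes always reported against chow and for the carbohydrate and fat effects, and the 5 smallest p-values of the interaction and the pairwise steps. The text names 120 of these genes, in 319 pairs of gene and comparison, and this subset was picked after the values were seen. Some genes the rule selects are withheld and not reported here; they stayed in the fit and in the list tests.

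The fit was tested on simulated data made from the real levels. For starch/oleate against chow it called 79.1% of genes with a simulated 1.5-fold change, 92.4% of those with 2-fold, 97.0% of those with 4-fold and 1.73% of the unchanged genes. For sucrose against starch with palmitate these were 68.7%, 87.7%, 98.5% and 1.37%, and for the Western diet against chow 60.3%, 92.4%, 98.5% and 2.74%. The simulation left the reference genes unchanged, made rises and falls equally likely and drew each gene independently. In the real data 9 of the 14 reference genes passed for starch/oleate and most calls were rises. The simulated rates therefore take the scaling as right and do not show the share of false calls in the real data. The negative control probes, with a mean count of 7.51 and a maximum of 21, set the level below which a gene cannot be told from background. The p-values measure the spread between samples, and the number of samples limits their precision.

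Alternatives fixed beforehand were TMM scaling, no filter, a mean count of at least 30, the replicate number as a block, only the compared groups in the fit, DESeq2 1.42.0 and the mean of the lymph node list as a covariate. This mean holds genes of the lymph node and B cell lists, so calls of these lists and genes lost under it are lost partly by construction. Added after the data were seen were leaving out 6 libraries (5 whose epithelium list score lay more than 3 median absolute deviations above the median, and a Western diet library with a high Clu count), leaving out each library in turn, the positive control ratio A over B as a covariate, and sucrose/palmitate libraries within the chow range of that ratio. Relations between diets were compared with 50 simulations of unchanged groups and with chow split into sets of 4 libraries. For each comparison 100 groupings of the samples were tried, the real one included. A gene is said to keep its call under every alternative when each alternative that tested it called it in the same direction. This covers the 9 alternatives that were run for single genes. With each library left out in turn, and within the chow range of the ratio, only counts of changed genes were taken. No sample was left out of the main results.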

Results

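The expression of immune genes was measured in epididymal white adipose tissue, the fat pad beside the testis, of 48 C3H/HeOuJ mice, an inbred strain, after 6 months on 6 diets. Chow was the control (n = 8). The 4 custom diets, with 42% of calories from carbohydrate and 42% from fat, crossed sucrose or starch with palmitate, a saturated fatty acid, or oleate, a monounsaturated one: sucrose/palmitate (n = 8), starch/palmitate (n = 7), sucrose/oleate (n = 9) and starch/oleate (n = 9). A commercial Western diet formed the last group (n = 7). The NanoString nCounter Mouse Immunology panel counts barcoded probes bound to RNA without amplification; it held 547 immune genes and 14 reference genes. Total counts of the gene probes per sample ran from 396391 to 888687, with a median of 635028. The single counts of the negative control probes had a mean of 7.51, so genes with a mean count below 10 were not tested, and 491 genes were. The ratio of the spiked-in positive controls A and B, which reads the assay and not the tissue, was 3.17 to 3.39 on chow, 2.99 to 3.56 on sucrose/palmitate, 2.92 to 3.16 on starch/palmitate, 2.92 to 3.07 on sucrose/oleate, 3.11 to 3.28 on starch/oleate and 3.27 to 3.43 on the Western diet. Values below are counts scaled to the reference genes, and differences are log2 differences ± SE from edgeR with all 48 samples in one fit; "rose" and "fell" are used for an adjusted p below 0.05.

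The title and design of the series pose the question of how the kind of carbohydrate and fat shapes fat tissue, and each diet was first set against chow. The lipid handling and adipocyte list fell, and the macrophage gene Emr1 rose, in all 5 fat-rich diets. Cfd, which encodes adipsin, a complement protease secreted by adipocytes, had a mean of 70397 ± 68829 (SD, n = 8) on chow and 4076 ± 2296 (SD, n = 9) on starch/oleate. Pparg, the master regulator of adipocyte differentiation, had 1025 ± 371 (SD, n = 8) on chow and 365 ± 46.2 (SD, n = 9) on starch/oleate. Emr1, the gene of the macrophage marker F4/80, went from 1813.5 ± 718 on chow to 5199.5 ± 788 on starch/oleate. Across the 5 diets, 38 genes rose in every one, among them Emr1, Itgax, Cd14, Cd9, Lair1, Cxcl10 and Tgfbr1. Another 6 fell in every one: Cfd, Pparg, Cd1d1, C9, Bcap31 and Irak2. Some of these calls were lost under alternative settings, as given for each diet below. A rise in at least 1 diet was found for 284 genes and a fall for 74, with 3 genes in both counts, Cd97, Fcgr2b and Il2ra, which were named after their values were seen. Any difference among the 6 groups was found for 318 of the 491 genes.

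**Figure D1:**
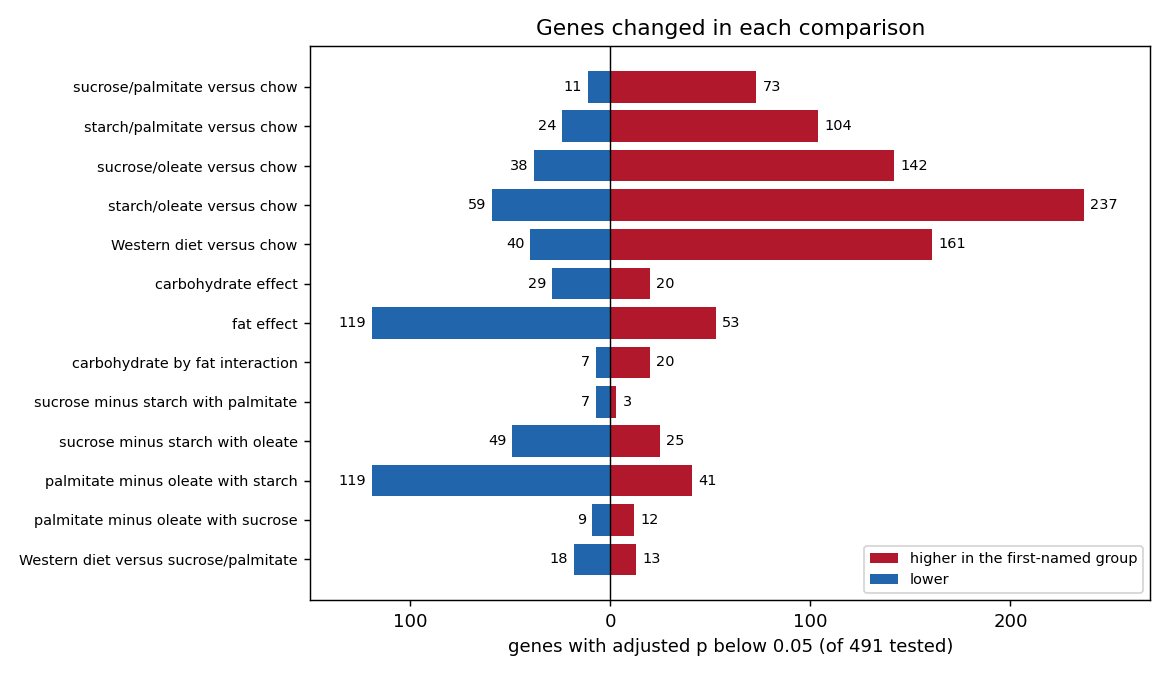
Number of genes with an adjusted p below 0.05 in each comparison (horizontal axis, of 491 tested), with genes higher in the first-named group to the right in red and lower to the left in blue. Starch/oleate against chow had the longest bars, with 237 genes higher and 59 lower; with TMM scaling these were 164 and 120.

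Rises outnumbered falls against chow in all 5 diets with both scalings, by less with TMM scaling. With reference gene scaling the median difference of all 491 genes from chow was 0.20 for sucrose/palmitate, 0.24 for starch/palmitate, 0.19 for sucrose/oleate, 0.34 for starch/oleate and 0.25 for the Western diet. With TMM scaling, which sets most genes to no difference, these medians were 0.07, 0.11, 0.03, 0.06 and 0.10. List medians below are therefore also given relative to the median of all genes. The gene list test, fry, is directional and self-contained: it asks whether the members of a list move on balance one way and does not compare them with other genes. It was run on 24 lists fixed before the data were examined, and its p was adjusted over the lists.

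**Figure D2:**
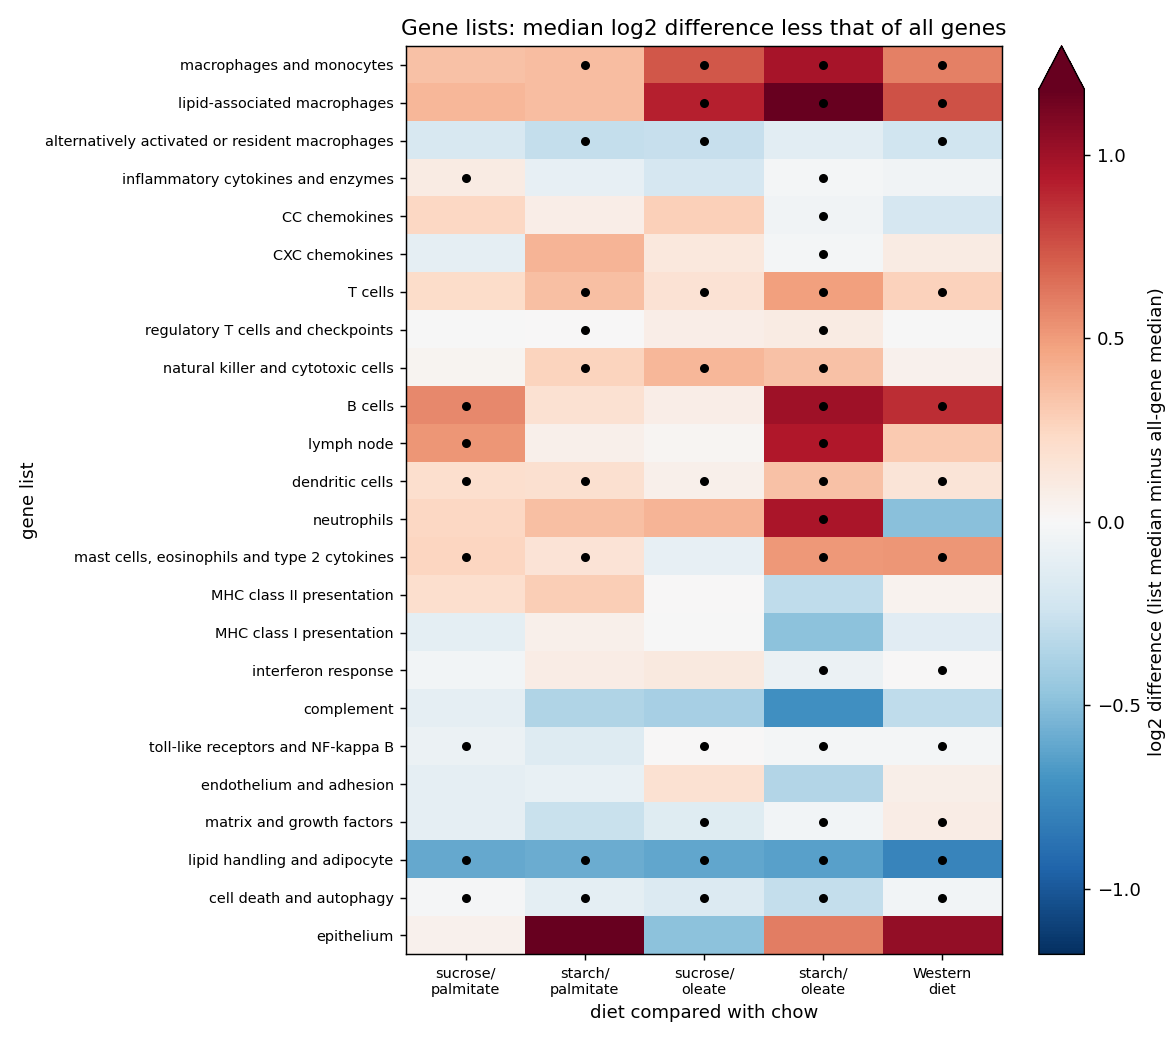
Median log2 difference from chow of the members of each gene list less the median of all genes (colour), for the 5 fat-rich diets (columns) and 24 lists (rows); a dot marks an adjusted p below 0.05 by fry. The lipid handling and adipocyte list has a dot in all 5 columns, with relative medians from -0.77 to -0.58; the epithelium list on starch/palmitate, at 1.76, lies beyond the colour scale, which ends at the next largest value.

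With sucrose/palmitate (n = 8, against 8 on chow), the adipocyte list fell and the B cell list rose. C9, a component of the complement pore, fell by 1.58 ± 0.33 (adjusted p = 0.0020), below the chow mean in 8 of 8 libraries. Cfb, complement factor B, fell by 0.74 ± 0.14 (adjusted p = 0.00052), in 8 of 8. Stat4, the signal transducer of interleukin 12, was higher by 2.07 ± 0.48 on average (adjusted p = 0.0055), but a single library, replicate 4, held 1191 counts and the others at most 61.4. Ptgs2, which encodes cyclooxygenase 2, had 9674 counts in replicate 3 and at most 82.5 in the others.

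In the lipid handling and adipocyte list, 3 of 6 measured genes fell with sucrose/palmitate, 0 rose and 3 did not pass, and adjusted over the list alone it was also 3. They were Cfd (-1.25 ± 0.45), Pparg (-0.56 ± 0.15) and Cd36, the fatty acid translocase (-0.43 ± 0.14). The list had a median of -0.40, or -0.60 relative to all genes (fry adjusted p = 3.4e-05). In the B cell list 8 of 11 rose, 0 fell and 3 did not pass (8 adjusted over the list alone, median 0.77, relative 0.57; adjusted p = 0.016). Its member Cd79b, part of the B cell receptor complex, rose by 1.35 ± 0.37, and Ms4a1, which encodes CD20, rose by 1.40 ± 0.43. Both were highest in replicates 1, 7 and 8, where Ms4a1 had 255.9, 344.4 and 196.7 counts, while the other 5 libraries had 40.9 to 95 and chow had 23.9 to 83.9. The lymph node list, which shares 5 genes with the B cell list, had 6 of 13 higher (8 adjusted over the list alone; adjusted p = 0.027). In the dendritic cell list 3 of 11 rose (5 adjusted over the list alone; adjusted p = 0.016): Itgax, the integrin CD11c (1.16 ± 0.33), Cd83, an activation marker (0.71 ± 0.23), and the chemokine Ccl22 (0.81 ± 0.23). The macrophage list did not pass as a whole (adjusted p = 0.075), though 5 of its 19 genes rose (7 adjusted over the list alone), among them Emr1 (0.71 ± 0.26). Of the classical cytokines, Tnf (0.59 ± 0.27), Il1b (0.38 ± 0.48) and Il6 (-0.23 ± 0.26) did not pass.

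In all, 73 genes rose and 11 fell with sucrose/palmitate, and with TMM scaling 34 and 26. The count was 10 with the lymph node list as a covariate, 40 with the positive control ratio as a covariate, 13 with only the 2 sucrose/palmitate libraries in the chow range of that ratio, and 14 with only these 2 groups in the fit; it was 25 without sucrose/palmitate replicate 1, 42 without its replicate 7, and 48, 32, 38 and 53 without chow replicates 2, 4, 6 and 8. With TMM scaling the inflammatory, lymph node, mast cell, toll-like receptor and cell death lists lost their calls, the first with an adjusted p of 0.12 and the lymph node list with 0.060, and Emr1 and Cd83 did not pass. With the lymph node list as a covariate those 5 and the B cell list (median 0.15, adjusted p = 0.30) and the dendritic cell list (adjusted p = 0.30) lost theirs. For the lymph node and B cell lists this loss comes partly by construction, since the covariate holds their genes. With the positive control ratio the inflammatory (0.057), lymph node (0.064), mast cell (0.091) and toll-like receptor (0.091) lists lost their calls, the last with the replicate block too (0.061). The adipocyte list kept its call throughout, but Cfd lost its own without a filter (edgeR adjusted p = 0.051), with the replicate block (0.10), with only these groups (0.12), with the lymph node covariate (0.16) and with the positive control ratio (0.053). With only these groups Pparg (0.064) and C9 (0.057) did not pass, and with the lymph node covariate neither did Pparg (0.10), Cd36 (0.080) and Cd1d1 (0.20). Of the 22 named genes that passed, 2 did so under every alternative.

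With starch/palmitate (n = 7), the T cell and macrophage lists rose, and the resident macrophage list fell. Cxcl10, an interferon-induced chemokine that draws T cells, rose by 2.01 ± 0.39 (adjusted p = 0.00035), above the chow mean in 7 of 7 libraries. The checkpoint receptors Tigit (1.56 ± 0.32) and Pdcd1 (1.71 ± 0.35) rose, each with an edgeR adjusted p of 0.00053, in 7 and 6 of 7 libraries. Their chow means (8.01 and 10.9) lay near that of the negative controls there (7.48), so the sizes of these rises are uncertain. The scavenger receptor Cd163, a marker of resident macrophages, fell by 0.95 ± 0.25 (adjusted p = 0.0049), in 7 of 7. The largest fold changes were in epithelial genes, Defb1 (6.21 ± 1.51), which encodes a beta-defensin, and Pigr (4.96 ± 1.05), which carries IgA across epithelia; 2 of the 7 libraries, replicates 1 and 3, stood apart in the epithelium list.

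In the T cell list 8 of 19 genes rose with starch/palmitate, 0 fell and 11 did not pass (9 adjusted over the list alone, median 0.59, relative 0.35; adjusted p = 0.011). They included Cd3e (1.25 ± 0.34) and Cd3d (1.04 ± 0.23) of the T cell receptor complex and the coreceptor genes Cd8a (1.22 ± 0.33) and Cd8b1 (1.43 ± 0.34). On chow Cd8a had a mean of 7.20, below the 7.48 of the negative controls there, so the size of its rise is uncertain. In the natural killer and cytotoxic list 5 of 17 rose (8 adjusted over the list alone; adjusted p = 0.011), with the activating receptor Klrk1 at 0.95 ± 0.23. The macrophage list had 9 of 19 higher (9 adjusted over the list alone, median 0.61, relative 0.36; adjusted p = 0.040), among them the Fc receptors Fcgr1 (1.24 ± 0.30) and Fcgr4 (1.84 ± 0.38). The resident macrophage list had 3 of 7 lower, 0 higher and 4 not passed (3 adjusted over the list alone; adjusted p = 0.044): Cd163, the lectin Cd209g (-0.84 ± 0.24) and the chemokine Ccl24 (-0.75 ± 0.23). In complement 5 of 25 fell and 2 rose, and the directional test did not pass (adjusted p = 0.11); C2 fell by 0.91 ± 0.19 and C3, the central component, by 0.52 ± 0.17. The adipocyte list had 3 of 6 lower (3 adjusted over the list alone, median -0.34, relative -0.58; adjusted p = 1.1e-05), with Cfd at -1.92 ± 0.48. H2-Ab1, a chain of MHC class II, rose by 0.70 ± 0.24, while its list did not pass (adjusted p = 0.075). Tnf (0.43 ± 0.28) and Il1b (0.71 ± 0.49) did not pass.

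In all, 104 genes rose and 24 fell with starch/palmitate, and with TMM scaling 74 and 52, where the macrophage (adjusted p = 0.073), regulatory T cell, dendritic cell, mast cell and cell death lists lost their calls and the complement list was called down (adjusted p = 0.0093). The macrophage list also lost its call with the replicate block (adjusted p = 0.062), with only these groups (0.098), with the lymph node covariate (0.073) and without 6 libraries set apart (0.057). The resident macrophage list lost its call with the block (0.062), with only these groups (0.058) and without the 6 libraries (median 0.0191, adjusted p = 0.11), and with only these groups the T cell (0.073) and cytotoxic (0.056) lists did. With the positive control ratio as a covariate 2 genes were called and 0 of the 29 named genes that passed kept their call. The 128 genes called without it kept their sign, with a median size of 0.60, from 0.73, and a median SE of 0.29, from 0.22. Of the lists, those of T cells (median 0.60, from 0.59; adjusted p = 0.39), cytotoxic cells (0.30, from 0.50; 0.49), macrophages (0.39, from 0.61; 0.49) and resident macrophages (-0.07, from -0.03; 0.39) lost their calls, as did the regulatory T cell, dendritic cell, mast cell and cell death lists, while the adipocyte list kept its own (-0.38, from -0.34; adjusted p = 0.00025). The ratio of each starch/palmitate library lay below that of each chow library, so assay run and diet cannot be told apart here. This holds for the adipocyte list too, since the covariate had no overlapping libraries to separate them. H2-Ab1, Defb1, Pigr and H2-Q10 lost their calls without the 6 libraries, and Ceacam1 was at -0.12 then.

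With sucrose/oleate (n = 9), the macrophage lists rose and the resident macrophage and adipocyte lists fell. Tgfbr1, a receptor of transforming growth factor beta, rose by 1.34 ± 0.13 (adjusted p = 6.5e-11), and Plau, the urokinase plasminogen activator, by 1.14 ± 0.13 (adjusted p = 1.6e-08); both lay above the highest chow library in 9 of 9. The collagen receptor Lair1 rose by 2.02 ± 0.27 (adjusted p = 3.3e-07), likewise in 9 of 9. Trem2, the lipid-sensing receptor of lipid-associated macrophages, rose by 1.24 ± 0.29 (adjusted p = 0.00098). Marco, a scavenger receptor of macrophages, fell by 2.06 ± 0.52 (adjusted p = 0.0016), below the chow mean in 9 of 9.

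The macrophage list had 14 of 19 genes higher, 1 lower and 4 not passed with sucrose/oleate (14 and 1 adjusted over the list alone, median 0.92, relative 0.73; adjusted p = 0.0020), including Emr1 (1.14 ± 0.25), Cd14 (1.01 ± 0.20) and Ly86 (1.09 ± 0.22), which act in the sensing of endotoxin. The lipid-associated macrophage list had 4 of 5 higher (4 adjusted over the list alone, median 1.11, relative 0.92; adjusted p = 0.00019): Itgax rose by 1.97 ± 0.33 and the tetraspanin Cd9 by 1.06 ± 0.17, while Cd36 was at -0.16 ± 0.13. The resident macrophage list had 3 of 7 lower (3 adjusted over the list alone, median -0.08, relative -0.27; adjusted p = 0.0040), with Ccl24 at -1.20 ± 0.22 and Cd163 at -0.97 ± 0.23. In the cytotoxic list 7 of 17 rose (10 adjusted over the list alone; adjusted p = 0.0015), among them the activating receptor Klra8 (1.63 ± 0.24), granzyme A, Gzma (1.22 ± 0.26), and the chemokine Xcl1 (0.82 ± 0.20). The adipocyte list had 2 of 6 lower, 0 higher and 4 not passed (2 adjusted over the list alone, median -0.42, relative -0.62; adjusted p = 1.1e-06): Cfd fell by 2.37 ± 0.44 and Pparg by 0.76 ± 0.15. In the toll-like receptor and NF-kappa B list 11 of 26 rose and 2 fell (12 and 3 adjusted over the list alone, relative median 0.00), with Tlr1 at 1.26 ± 0.23 and the inhibitor Tnfaip3 at 0.86 ± 0.13. Cxcl13 (2.95 ± 0.87), S100a9 (2.56 ± 0.80) and Ccl12 (1.79 ± 0.50) were highest in replicate 2, which held 5490 counts of Cxcl13 against at most 182 in the others. Tnf rose by 0.72 ± 0.26 and Il1b did not pass (0.90 ± 0.46).

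In all, 142 genes rose and 38 fell with sucrose/oleate, and with TMM scaling 108 and 69, where Tnf and the T cell (adjusted p = 0.15), toll-like receptor, matrix and cell death lists no longer passed and the complement list was called down (adjusted p = 0.0090). With the positive control ratio as a covariate 30 genes were called, and the macrophage (median 0.75, from 0.92; adjusted p = 0.24), lipid-associated macrophage (0.91, from 1.11; 0.078), resident macrophage (-0.12, from -0.08; 0.10), cytotoxic (0.24, from 0.59; 0.45), T cell (0.37, from 0.36; 0.57) and toll-like receptor (0.13, from 0.20; 0.21) lists lost their calls, as did the dendritic cell, matrix and cell death lists. The adipocyte list kept its call (-0.27, from -0.42; adjusted p = 0.00023). Of the 180 genes called without the covariate 179 kept their sign, with a median size of 0.55, from 0.72, and a median SE of 0.28, from 0.19. Every alternative kept 13 of the 31 named genes that passed. As for that ratio, all 9 libraries lay below its chow range, so assay run and diet cannot be told apart here either, the adipocyte list included.

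Starch/oleate (n = 9) had the highest count of the 5 diets, with the macrophage, lymphocyte and mast cell lists higher and the adipocyte list lower. Cfd fell by 4.11 ± 0.48, or 17.3-fold (adjusted p = 2.8e-09), and Pparg by 1.49 ± 0.15, or 2.81-fold (adjusted p = 9.9e-11). Cd1d1, which presents lipids to natural killer T cells, fell by 2.40 ± 0.21, or 5.29-fold (adjusted p = 2.1e-12). Trem2 rose by 1.66 ± 0.30, or 3.16-fold (adjusted p = 8.6e-06), and Emr1 by 1.52 ± 0.26, or 2.87-fold (adjusted p = 3.4e-06). Each of these 5 genes lay beyond all chow libraries in 9 of 9.

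**Figure D3:**
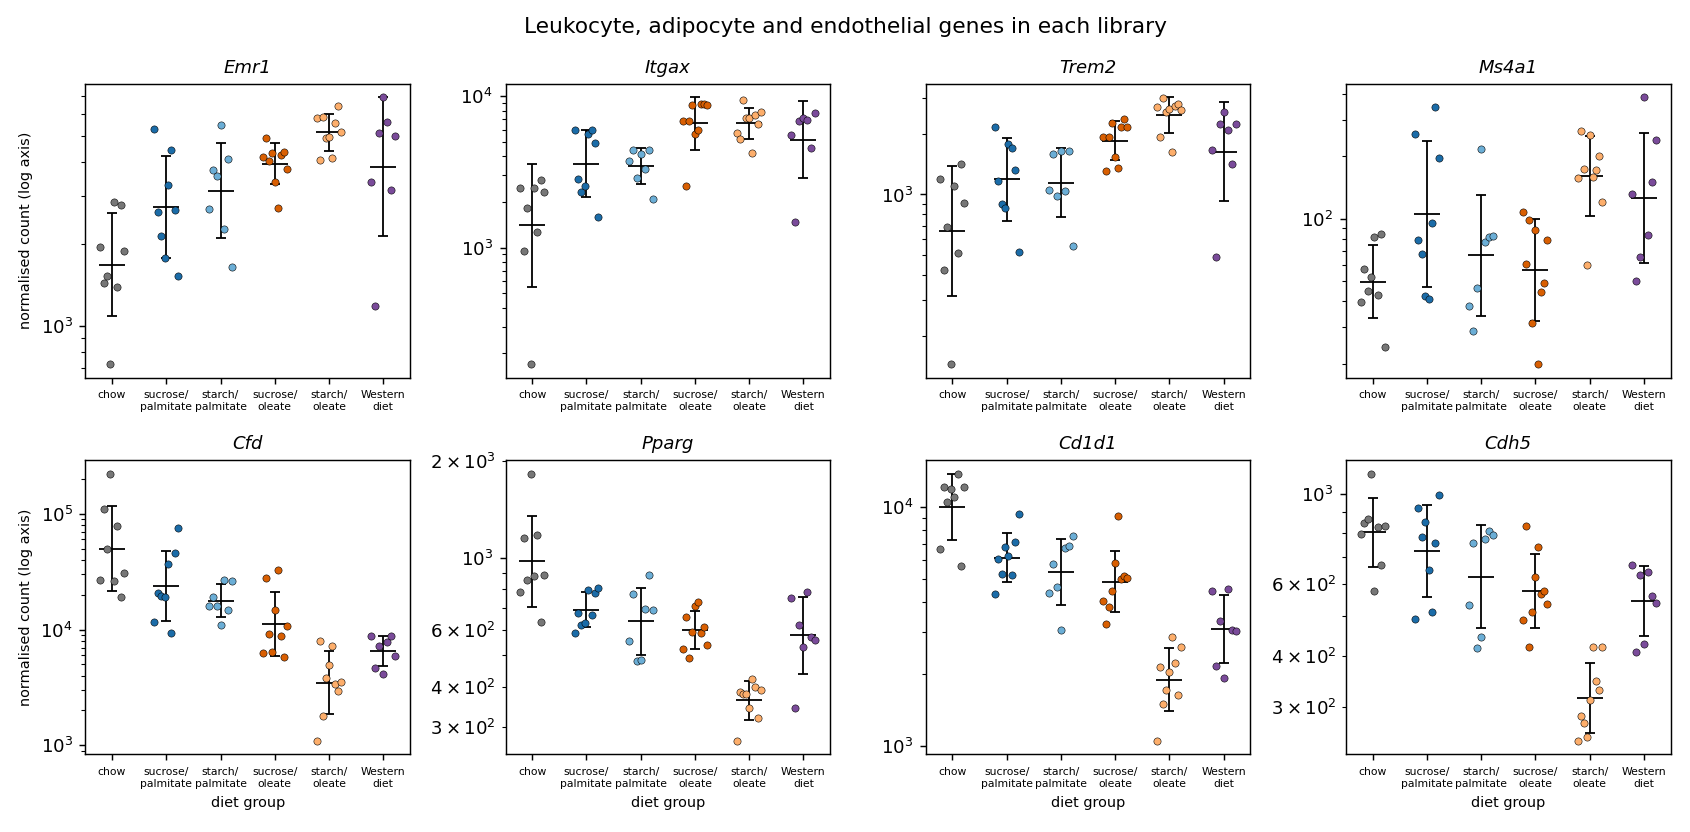
Normalised counts (vertical, log axis) of 8 genes in each of the 48 libraries (points) by diet group; bars give the mean and SD of the log values. On starch/oleate, mean Cfd was 4076 against 70397 on chow, and mean Emr1 was 5199.5 against 1813.5.

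Of the myeloid lists with starch/oleate, that of macrophages had 17 of 19 genes higher, 0 lower and 2 not passed (17 adjusted over the list alone, median 1.31, relative 0.97; adjusted p = 7.6e-06). Msr1, a scavenger receptor (1.73 ± 0.27), and Tyrobp (1.52 ± 0.27) and Fcer1g (1.45 ± 0.24), signalling adaptors of myeloid receptors, were among them. The lipid-associated macrophage list had 4 of 5 higher (4 adjusted over the list alone, median 1.52, relative 1.18; adjusted p = 7.6e-06), with Itgax at 1.92 ± 0.33 and Cd9 at 1.22 ± 0.17. Resident macrophage genes went both ways, 2 of 7 higher and 3 lower; the median was 0.22, the mean -0.32 and the direction of the test down without passing (adjusted p = 0.12), though with TMM scaling the list was called down (adjusted p = 9.8e-06). Cd163 fell by 1.20 ± 0.23 and Ccl24 by 1.48 ± 0.22. The neutrophil list had 4 of 7 higher (4 adjusted over the list alone; adjusted p = 0.0075), with S100a9, a calgranulin subunit, at 2.62 ± 0.80 (1455.8 and 672.7 counts in replicates 1 and 6, at most 251 in the others) and the receptor Csf3r at 1.30 ± 0.27. Among mast cell, eosinophil and type 2 genes 5 of 8 rose (5 adjusted over the list alone, median 0.85, relative 0.51; adjusted p = 2.7e-07): the IgE receptor chain Fcer1a (1.38 ± 0.22), the stem cell factor receptor Kit (1.01 ± 0.21) and the interleukin 33 receptor Il1rl1 (1.12 ± 0.19) were 3 of them. Gata3, a transcription factor of type 2 lymphocytes and also of epithelia, rose by 3.37 ± 0.92 and was highest in the 2 libraries that stood apart in the epithelium list, replicates 2 and 6.

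The lymphocyte lists rose with starch/oleate too. In the B cell list 10 of 11 rose (11 adjusted over the list alone, median 1.34, relative 1.00; adjusted p = 2.7e-06), among them the inhibitory lectin Cd22 (1.73 ± 0.26) and the adaptor Blnk (1.53 ± 0.22). The lymph node list had 10 of 13 higher (10 adjusted over the list alone, median 1.29, relative 0.95; adjusted p = 0.00029), with Cxcl13, the chemokine of B cell follicles, at 2.14 ± 0.84. In the T cell list 12 of 19 rose (12 adjusted over the list alone, median 0.83, relative 0.48; adjusted p = 4.0e-05), including Cd3e (1.32 ± 0.33), Cd4 (1.23 ± 0.24) and Cd8a (0.96 ± 0.32, of uncertain size with 7.20 counts on chow). In the cytotoxic list 11 of 17 rose (11 adjusted over the list alone; adjusted p = 2.7e-05), with Klra8 at 2.09 ± 0.24 and Xcl1 at 1.20 ± 0.20. With the lymph node list as a covariate Cd3e, Cd4 and Cd8a did not pass.

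Signalling and structural lists were mixed with starch/oleate. In the inflammatory list 6 of 13 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.32, relative -0.02; adjusted p = 0.00012): Tnf rose by 1.01 ± 0.26, Il1b by 1.06 ± 0.46 (160.9 counts in replicate 1, at most 64.3 in the others) and Il1rn, the interleukin 1 receptor antagonist, by 1.54 ± 0.33, and Il6 did not pass (-0.30 ± 0.25). Of 15 CC chemokines 7 rose and 1 fell (6 and 1 adjusted over the list alone, relative median -0.04; adjusted p = 0.00096), with Ccl3 at 1.49 ± 0.28, Ccl4 at 1.16 ± 0.24 and Ccl2, the monocyte chemoattractant, at 0.52 ± 0.23. Toll-like receptor and NF-kappa B genes had 15 of 26 higher and 2 lower (15 and 2 adjusted over the list alone, relative median -0.02; adjusted p = 7.6e-06), among them Tlr1 (1.48 ± 0.23) and Tlr2 (1.14 ± 0.18). In the matrix list 6 of 14 rose and 2 fell (6 and 2 adjusted over the list alone), with Tgfb1 at 1.01 ± 0.16 and Tgfbr1 at 1.38 ± 0.13. In the adipocyte list 2 of 6 fell and 1 rose (2 and 1 adjusted over the list alone, median -0.30, relative -0.64; adjusted p = 2.7e-06); the gene that rose was Tfrc, the transferrin receptor (1.29 ± 0.20), and Cd36 did not pass (-0.27 ± 0.13). Of 25 complement genes 10 fell and 7 rose (10 and 7 adjusted over the list alone), so that the test of change in either direction passed (adjusted p = 2.7e-08) and the directional test did not (adjusted p = 0.097). Cdh5, the cadherin of endothelial junctions, fell by 1.35 ± 0.16 in a list of 9 endothelial genes with 3 higher and 3 lower, which was called down with TMM scaling (adjusted p = 0.00057). The cell death list was called up (adjusted p = 0.00044) with 5 of 13 higher and 1 lower; its death receptor Fas fell by 1.08 ± 0.16, and with TMM scaling the list median was -0.23 and the call was down.

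In all, 237 genes rose and 59 fell with starch/oleate, and with TMM scaling 164 and 120; Il1b and Ccl2 lost their calls then, as did the inflammatory (adjusted p = 0.051), CXC chemokine, regulatory T cell, neutrophil (adjusted p = 0.054), interferon, toll-like receptor and matrix lists. With the lymph node list as a covariate 186 were called, and the inflammatory (adjusted p = 0.20), CC chemokine (0.30), neutrophil (0.20), dendritic cell (0.073), interferon (0.76), matrix (0.12), cell death (0.13) and lymph node (0.84) lists lost their calls. The interferon list also lost its call without the 6 libraries set apart (0.084) and with the positive control ratio (0.12). Of 48 named genes that passed, 36 did so under every alternative. In the fit reported, 9 of the 14 reference genes themselves passed the test. Against chow this was also 9 for the Western diet, 5 for sucrose/oleate, 4 for starch/palmitate and 1 for sucrose/palmitate. It was 7 for the fat effect, 3 for the carbohydrate effect and 2 for the interaction. Sucrose minus starch with oleate had 6, as did palmitate minus oleate with starch, and the remaining comparisons had 0.

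With the Western diet (n = 7), the adipocyte and resident macrophage lists fell, and the macrophage, B cell and interferon lists rose. C9 fell by 2.75 ± 0.38 (adjusted p = 5.1e-07), but its mean of 5.43 lay below that of the negative controls in this group (7.07), so the size of the fall is uncertain. Cfd fell by 3.38 ± 0.51, or 10.4-fold (adjusted p = 2.3e-06), and both lay below all chow libraries in 7 of 7. Stat2, a transducer of type I interferon signals, rose by 0.76 ± 0.17 (adjusted p = 0.00045), and Mx1, an antiviral GTPase induced by interferon, by 0.55 ± 0.11 (adjusted p = 0.00021), both in 7 of 7.

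The macrophage list had 11 of 19 genes higher and 2 lower on the Western diet (15 and 2 adjusted over the list alone, median 0.85, relative 0.59; adjusted p = 0.0083): Emr1 rose by 1.26 ± 0.27 and Cd14 by 1.00 ± 0.21, and Marco fell by 1.46 ± 0.55. The lipid-associated macrophage list had 4 of 5 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0070), with Itgax at 1.69 ± 0.34, Trem2 at 1.18 ± 0.31 and Cd36 at -0.63 ± 0.14. The resident macrophage list had 3 of 7 lower (3 adjusted over the list alone); its median was 0.02, its mean -0.46 and its call down (adjusted p = 0.0043), with Cd163 at -1.33 ± 0.25 and Cd209g at -1.27 ± 0.24. In the B cell list 8 of 11 rose (8 adjusted over the list alone, median 1.12, relative 0.87; adjusted p = 0.0020), with Cd22 at 1.30 ± 0.27. In the interferon list 8 of 17 rose and 0 fell (8 adjusted over the list alone, relative median 0.00; adjusted p = 0.022), Cxcl10 by 1.76 ± 0.39. The mast cell and type 2 list had 5 of 8 higher (5 adjusted over the list alone; adjusted p = 0.0010), with Il1rl1 at 0.99 ± 0.20 and Kit at 0.77 ± 0.22. The adipocyte list had 3 of 6 lower and 1 higher (3 and 1 adjusted over the list alone, median -0.52, relative -0.77; adjusted p = 6.0e-08), with Pparg at -0.79 ± 0.16. The gene higher in that list was Clu, the chaperone clusterin, at 3.38 ± 0.73: replicate 2 held 173666 counts and the other 6 libraries at most 3378. Tnf (0.63 ± 0.28) and Il1b (0.50 ± 0.50) did not pass.

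In all, 161 genes rose and 40 fell with the Western diet, and with TMM scaling 113 and 58, where the interferon (adjusted p = 0.12), T cell, matrix and cell death lists lost their calls. With only these groups in the fit the macrophage (adjusted p = 0.056) and lipid-associated macrophage (0.057) lists lost theirs, and with the lymph node covariate the macrophage (0.082) and interferon (0.20) lists did. Without the 6 libraries the resident macrophage list did not pass (median 0.0771, adjusted p = 0.053). All alternatives kept 23 of the 30 named genes that passed. The calls of C4bp (5.71 ± 1.28), Clu and Tcf7 (2.17 ± 0.60) rested on replicate 2, which held 15238.8 counts of C4bp against 7.4 in replicate 6. Those of Defb1 (3.61 ± 1.36) and Gata3 (2.91 ± 0.93) rested on replicates 2 and 6. Without 6 libraries set apart, these 2 included, Clu was at -0.48, Defb1 at -1.21 and Tcf7 at -0.05, and C4bp and Gata3 did not pass.

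The epithelium list was included because epididymis can be left on this fat pad. Its 6 measured genes did not pass as a list in any comparison. Defb1 had a mean of 41.9 ± 72.6 (SD, n = 8) on chow and 9.11 ± 3.65 (SD, n = 9) on sucrose/oleate, but reached 17524.5 in starch/palmitate replicate 3. Libraries whose list score lay more than 3 median absolute deviations above the median numbered 2 of 7 on starch/palmitate, 2 of 9 on starch/oleate, 1 of 7 on the Western diet and 0 in the other 3 groups.

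**Figure D4:**
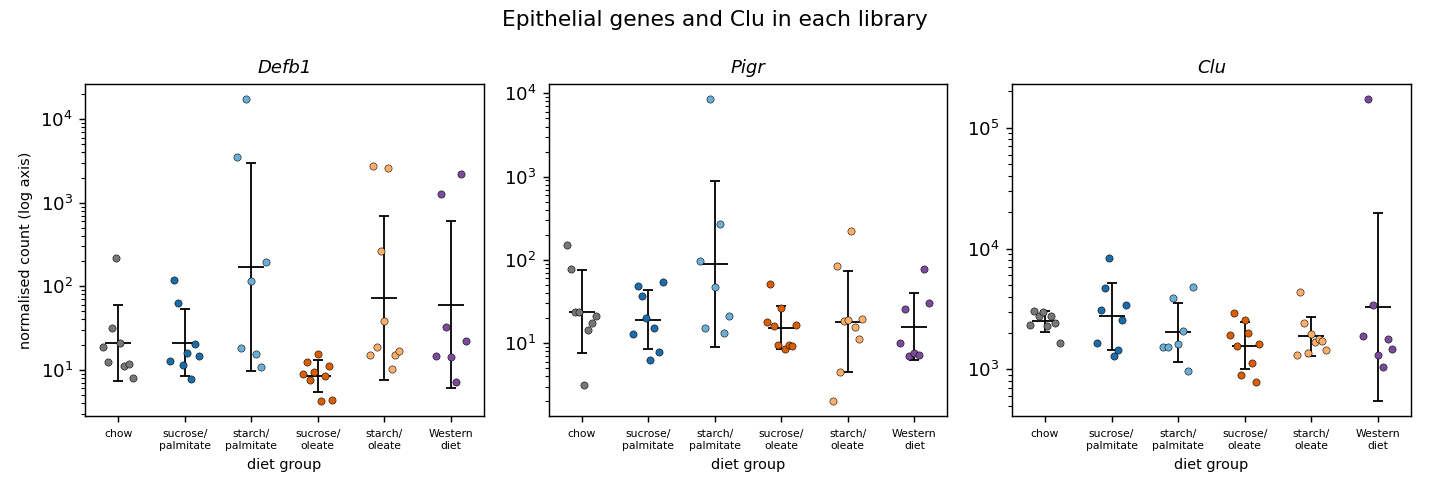
Normalised counts (vertical, log axis) of Defb1, Pigr and Clu in each of the 48 libraries (points) by diet group; bars give the mean and SD of the log values. Defb1 reached 17524.5 in a starch/palmitate library, while the highest chow library had 220.6; Clu reached 173666 in a Western diet library.

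The responses of the diets were then compared with each other across the 491 genes. Genes are not independent replicates, and contrasts that share the chow libraries correlate even when nothing differs, so each r was set beside a simulation of unchanged groups. Shared calls are given beside the number expected if the calls of both diets were independent, which does not allow for the shared chow libraries. The simulation had 0 shared calls, but it drew each gene independently of the others. Genes that vary together between mice were not simulated, so the simulated agreement may understate what chance gives. Starch/oleate and the Western diet correlated at r = 0.70 against 0.50 in the simulation, and at 0.59 with separate chow libraries for each; 135 genes rose in both (77.7 if independent) and 30 fell in both (4.81). Sucrose/oleate and starch/oleate shared 134 rises (68.5 if independent) and 34 falls (4.57). Starch/palmitate and sucrose/oleate correlated at r = 0.36, below the 0.50 of the simulation, but their covariance was 0.13 against 0.04 in the simulation, 83.1% of genes differed from chow in the same direction against 66.8%, and they shared 67 rises (30.1 if independent) and 18 falls (1.86).

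The custom diets ask whether the carbohydrate matters at a given fat. Over both fats, the adipocyte genes Cfd and Pparg and the endothelial Cdh5 were higher with sucrose (n = 17) than with starch (n = 16), and Cd4, Tigit and 4 epithelial genes were lower. Cfd was higher by 1.21 ± 0.31 (adjusted p = 0.011), Pparg by 0.41 ± 0.11 (adjusted p = 0.011) and Cdh5 by 0.54 ± 0.11 (adjusted p = 0.00086). Cfd, Pparg and Cdh5 were each called with oleate alone, but were not among the 10 genes called with palmitate alone. Mean Pparg was 696 on sucrose/palmitate and 652 on starch/palmitate, against 605 on sucrose/oleate and 365 on starch/oleate. Mean Cfd was 29624 and 18614 on the palmitate diets, against 13643 and 4076 on the oleate diets. Cd1d1 was higher by 0.77 ± 0.15 (adjusted p = 0.00057) and Cd59b, an inhibitor of the complement pore, by 0.72 ± 0.14 (adjusted p = 0.00069). Sucrose/palmitate replicate 4 held 124 counts of Cd59b and the others of its group at most 49.9. The step of Cd1d1 was not alike for the fats (interaction -1.19). Its means were 5087 on sucrose/oleate and 1975 on starch/oleate, against 6299 on sucrose/palmitate and 5576 on starch/palmitate. Fcer1a, named below, had an interaction as well (1.04). Tigit was lower with sucrose (-1.05 ± 0.21, edgeR adjusted p = 0.00074), as were Cd4 (-0.62 ± 0.17) and the chemokine Ccl8 (-1.02 ± 0.32). The mean of Tigit on sucrose/palmitate (7.57) lay below that of the negative controls there (8.19), so the size of its difference is uncertain. The macrophage genes Emr1 (-0.28 ± 0.18), Itgax (0.10 ± 0.23) and Trem2 (-0.16 ± 0.21) did not pass. Of the 24 lists, the mast cell and type 2 list passed, downward, with 2 of 8 lower (3 adjusted over the list alone; adjusted p = 0.0096): Fcer1a at -0.53 ± 0.15 and Gata3 at -2.58 ± 0.62. That call was lost without a filter (adjusted p = 0.16), and with TMM scaling the endothelial list was called up (adjusted p = 0.0040). The T cell list had 5 of 19 lower (6 adjusted over the list alone) without passing as a list (adjusted p = 0.14). In the epithelium list 4 of 6 were lower (4 adjusted over the list alone), with Defb1 at -6.31 ± 1.06, Pigr at -3.47 ± 0.70 and Ceacam1 at -2.35 ± 0.45. The 4 custom-diet libraries that stood apart in this list were all starch-fed. The score reads only these 6 genes, and sucrose-fed libraries were high for others. Sucrose/palmitate replicate 3 held 9674.3 counts of Ptgs2 and 1062.7 of Gata3.

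In all, 20 genes were higher and 29 lower with sucrose than with starch, and with TMM scaling 29 and 25. The count fell to 30 with the replicate block, 24 without starch/palmitate replicate 3, 27 without its replicate 4, 32 and 25 without starch/oleate replicates 2 and 8, 28, 27 and 25 without sucrose/palmitate replicates 2, 4 and 8, and 25, 24 and 31 without sucrose/oleate replicates 5, 6 and 8; without the 6 libraries set apart Gata3 and Pigr did not pass and Mme was at 0.36, from -0.99 ± 0.33. Of 17 named genes that passed, 11 kept their call under every alternative.

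Over both carbohydrates, the macrophage lists were lower, and Cfd and Pparg higher, with palmitate (n = 15) than with oleate (n = 18). Cfd was higher with palmitate by 1.65 ± 0.31, or 3.15-fold (adjusted p = 9.2e-05), and Pparg by 0.52 ± 0.11 (adjusted p = 0.00032). Tgfbr1 was lower (-0.64 ± 0.09, adjusted p = 4.3e-06), as were Klra8 (-1.14 ± 0.17, adjusted p = 4.8e-06) and Il12rb2, a subunit of the interleukin 12 receptor (-0.82 ± 0.15, adjusted p = 4.5e-05). Tlr5, the receptor of flagellin, was higher (0.83 ± 0.16, adjusted p = 0.00015).

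In the macrophage list 12 of 19 genes were lower with palmitate, 0 higher and 7 not passed (12 adjusted over the list alone, median -0.53, relative -0.48; adjusted p = 0.024), among them Msr1 (-0.77 ± 0.19), Itgam, which encodes CD11b (-0.57 ± 0.16), and Emr1 (-0.53 ± 0.18). All 5 lipid-associated macrophage genes were lower (5 adjusted over the list alone, median -0.72, relative -0.67; adjusted p = 0.0030): Trem2 at -0.80 ± 0.21, Itgax at -0.87 ± 0.23, Cd9 at -0.49 ± 0.12, Tyrobp at -0.72 ± 0.19 and Cd36 at -0.24 ± 0.10. The toll-like receptor and NF-kappa B list had 9 of 26 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.018), with Tnfaip3 at -0.51 ± 0.09 and Ly96, the partner of toll-like receptor 4, at -0.48 ± 0.12. The matrix list had 5 of 14 lower (6 adjusted over the list alone; adjusted p = 0.018), with Tgfb1 at -0.51 ± 0.11 and the growth factor Pdgfb at -0.48 ± 0.09. Tnf (-0.36 ± 0.18), Il1b (-0.43 ± 0.32) and Ccl2 (-0.13 ± 0.17) did not pass. In all, 53 genes were higher and 119 lower with palmitate, and with TMM scaling 102 and 94; the toll-like receptor (adjusted p = 0.21) and matrix (adjusted p = 0.091) lists lost their calls then, Cd36 did not pass, and the resident macrophage (0.030), MHC class II (0.030) and MHC class I (0.040) lists were called up. With the replicate block the macrophage list did not pass (adjusted p = 0.058). Every alternative kept 21 of 26 named genes that passed.

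The test of whether the carbohydrate effect differed between the fats called 27 genes, 20 with a positive and 7 with a negative interaction. The mean positive control ratio was 3.25 on sucrose/palmitate and 3.20 on starch/oleate, the diets on the positive side of this contrast. It was 3.04 on starch/palmitate and 2.99 on sucrose/oleate, those on its negative side, so assay run and interaction were not told apart. Among B cell genes, the difference of sucrose minus starch was larger with palmitate than with oleate by 2.15 ± 0.52 for Cd79b (adjusted p = 0.015) and 2.20 ± 0.60 for Ms4a1 (adjusted p = 0.023), both of which were highest in replicates 1, 7 and 8 of the sucrose/palmitate group. It was also larger for Tfrc (1.40 ± 0.28, adjusted p = 0.0027) and for Il1a, an alarmin cytokine (1.83 ± 0.42, adjusted p = 0.011), whose mean on starch/palmitate (6.79) lay below that of the negative controls there (8.50), and smaller for Cd1d1 (-1.19 ± 0.29, adjusted p = 0.016). In the B cell list 6 of 11 passed, all positive (8 adjusted over the list alone, median 0.86, relative 0.74; adjusted p = 0.0095), and in the mast cell and type 2 list 2 of 8 (2 adjusted over the list alone; adjusted p = 0.0095), Kit (1.03 ± 0.29) and Fcer1a (1.04 ± 0.31). The lymph node list had 5 of 13 (7 adjusted over the list alone; adjusted p = 0.0095). With the lymph node covariate the B cell (0.28), mast cell (0.30) and lymph node (0.66) lists lost their calls, and the lymph node list did so without the 6 libraries too (0.060). TMM scaling called the MHC class I (0.022) and endothelial (0.035) lists down, and split the genes into 14 and 16; 6 genes were called with the lymph node list as a covariate and edgeR called 0 with the positive control ratio, where 78 had an unadjusted p below 0.05; DESeq2, without that covariate, called 33. Of the 16 named genes that passed, 0 kept their call under every alternative.

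With oleate as the fat, sucrose (n = 9) and starch (n = 9) differed in Pparg and in the endothelial, B cell and mast cell lists. Cd1d1 was higher with sucrose by 1.36 ± 0.20 (adjusted p = 5.3e-06), above all starch/oleate libraries in 9 of 9, and so was Pparg, by 0.73 ± 0.15 (adjusted p = 0.00042). Tfrc was lower (-1.57 ± 0.19, adjusted p = 1.3e-07), below the starch/oleate mean in 9 of 9. Endothelial genes had 4 of 9 higher and 0 lower (4 adjusted over the list alone, median 0.11, relative 0.25; adjusted p = 0.035): Cdh5 at 0.87 ± 0.15, Pecam1, which encodes CD31, at 0.61 ± 0.15 and Icam2 at 0.48 ± 0.14 were among them. In the B cell list 7 of 11 were lower (10 adjusted over the list alone, median -0.60, relative -0.46; adjusted p = 0.0039), with Ms4a1 at -1.43 ± 0.40 and Pax5, the B lineage transcription factor, at -1.20 ± 0.33. In the mast cell and type 2 list 4 of 8 were lower (4 adjusted over the list alone; adjusted p = 6.1e-05), with Fcer1a at -1.05 ± 0.21, Kit at -0.71 ± 0.20 and Gata3 at -3.78 ± 0.89, which was high in the starch/oleate libraries apart in the epithelium list. In all, 25 genes were higher and 49 lower, and with TMM scaling 50 and 34; 36 were called with the lymph node list as a covariate, 154 with only these groups in the fit and 114 without the 6 libraries set apart. The endothelial list lost its call without a filter (adjusted p = 0.053), with only these groups (0.057) and with the positive control ratio (0.12), and the B cell list with the lymph node covariate (0.51). TMM scaling called the MHC class I (0.018) and cell death (0.032) lists up. Every alternative kept 13 of 22 named genes that passed.

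With palmitate as the fat, sucrose (n = 8) and starch (n = 7) differed in 10 genes, 3 higher and 7 lower with sucrose. Tigit was lower (-1.60 ± 0.32, adjusted p = 0.0019), in 8 of 8 libraries; its mean with sucrose (7.57) lay below that of the negative controls (8.19), so the size is uncertain. Lower too was the interferon-induced chemokine Cxcl9 (-1.36 ± 0.39, adjusted p = 0.047). Il2ra, a chain of the interleukin 2 receptor, was higher by 0.56 ± 0.15 (adjusted p = 0.041), and Ski, a repressor of transforming growth factor signals, by 0.28 ± 0.08 (adjusted p = 0.042). Defb1 (-6.52 ± 1.53), Pigr (-5.67 ± 1.10) and Ceacam1 (-2.62 ± 0.67) of the epithelium list were lower, 3 of 6 (3 adjusted over the list alone). No list passed, and the smallest adjusted p was 0.80. Without starch/palmitate replicate 3, or without the 6 libraries set apart, edgeR called 0 genes, with 40 at an unadjusted p below 0.05 in each case; DESeq2, with all libraries, called 10. Without sucrose/palmitate replicate 7 it was 6. With only these groups in the fit edgeR called 0 (39 unadjusted), with the replicate block 1, with the positive control ratio 1 and with the lymph node list 16, and 9 of 100 groupings of the samples, the real one included, reached 10, so chance is not excluded. None of the 10 genes kept its call under every alternative.

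With starch as the carbohydrate, palmitate (n = 7) and oleate (n = 9) differed in the macrophage and B cell lists and in Cdh5. Cd1d1 was higher with palmitate by 1.50 ± 0.21 (adjusted p = 1.3e-06) and Cdh5 by 1.01 ± 0.16 (adjusted p = 1.4e-05), above the starch/oleate mean in 7 of 7 libraries, and Cfd by 2.19 ± 0.45 (adjusted p = 0.00038). Klra8 was lower (-1.39 ± 0.24, adjusted p = 4.8e-05), as was Tfrc (-1.49 ± 0.21, adjusted p = 1.3e-06). In the macrophage list 11 of 19 were lower and 0 higher (12 adjusted over the list alone, median -0.64, relative -0.50; adjusted p = 0.036), with Fcer1g at -1.002 ± 0.25 and Itgam at -0.88 ± 0.23, and in the B cell list 8 of 11 (10 adjusted over the list alone, median -0.78, relative -0.65; adjusted p = 0.0044), with Cd22 at -1.01 ± 0.26. H2-Q10, a class I molecule of liver, was higher by 3.53 ± 0.57 and Pigr by 4.87 ± 1.00. In starch/palmitate replicate 3 H2-Q10 had 8669 counts and Pigr 8628.7, against at most 390 and 272.7 in the other libraries of that group. In all, 41 genes were higher and 119 lower, and with TMM scaling 82 and 67, where the macrophage list lost its call (adjusted p = 0.074) and the MHC class II (0.028), MHC class I (0.0040), endothelial (0.0071), adipocyte (0.048) and cell death (0.0081) lists were called up. With the replicate block the macrophage list did not pass (0.061). With the lymph node list as a covariate 81 were called, and the macrophage (0.34) and B cell (0.070) lists lost their calls. Every alternative kept 13 of 18 named genes that passed.

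With sucrose as the carbohydrate, palmitate (n = 8) and oleate (n = 9) differed in 21 genes, 12 higher and 9 lower with palmitate. Tgfbr1 was lower (-0.61 ± 0.13, adjusted p = 0.0078), as were Lair1 (-0.99 ± 0.26), Klra8 (-0.89 ± 0.23) and Plau (-0.47 ± 0.13), each in 8 of 8 libraries. The chemokine Ccl24 was higher by 1.00 ± 0.22 (adjusted p = 0.0079), in 8 of 8, and Marco by 1.85 ± 0.51 (adjusted p = 0.034), in 7 of 8. Stat4 (1.70 ± 0.45), Cd46 (1.19 ± 0.31) and Ptgs2 (4.58 ± 1.33) were high in single sucrose/palmitate libraries. No list passed, and the smallest adjusted p was 0.13. With TMM scaling 17 were higher and 19 lower, and the resident macrophage list was called up (adjusted p = 0.013); 1 was called with the positive control ratio as a covariate, 3 with the replicate block, 36 with DESeq2, 77 with the lymph node list and 48 without the 6 libraries set apart. The count was 9, 5, 12 and 7 without sucrose/palmitate replicates 3, 4, 7 and 8, and 7, 3, 6 and 3 without sucrose/oleate replicates 1, 4, 7 and 8. Of 12 named genes that passed, 1 kept its call under every alternative.

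The Western diet (n = 7) was set against sucrose/palmitate (n = 8), the custom diet with sugar and a saturated fat. Cfd and Cd1d1 were lower on the Western diet: Cfd fell by 2.13 ± 0.48, or 4.38-fold (adjusted p = 0.0058), below all sucrose/palmitate libraries in 7 of 7, and Cd1d1 by 0.97 ± 0.22 (adjusted p = 0.0058). Il2ra was lower (-0.92 ± 0.15, adjusted p = 6.1e-05), as were Ltb4r1, the leukotriene B4 receptor (-0.93 ± 0.22), and the resident macrophage lectin Cd209g (-1.01 ± 0.24). Smad3, a transducer of transforming growth factor signals, was higher (0.45 ± 0.07, adjusted p = 6.1e-05), in 7 of 7, and so was Runx1, a transcription factor of blood lineages (0.74 ± 0.19). In the resident macrophage list 3 of 7 were lower (3 adjusted over the list alone), but no list passed; the smallest adjusted p was 0.11. With TMM scaling the resident macrophage list was called down and the toll-like receptor list up (adjusted p = 0.0080 for both). Clu (2.99 ± 0.72) and C4bp (4.45 ± 1.20) were high in Western diet replicate 2, and without the 6 libraries set apart they were at -0.87 and -0.96. In all, 13 genes were higher and 18 lower, 31 together, and 5 of 100 groupings of the samples, the real one included, reached that count, so chance is not excluded. The count was 16 with only these groups in the fit, 14 with the replicate block, 58 without Western diet replicate 2 and 18, 17, 14 and 18 without its replicates 1, 3, 5 and 7, 15 and 17 without sucrose/palmitate replicates 4 and 8, and 81 without the 6 libraries set apart. Every alternative kept 7 of 15 named genes that passed.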

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

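The tests of epithelial genes, of scaling, of adipocyte share and of assay run for starch/palmitate and sucrose/oleate were chosen only after the result was seen; the other tests below were written down before their result was seen, though leaving out the 6 libraries and the positive control ratio were themselves added once the data had been examined. Values are normalised counts unless given as log2 differences.

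Epithelial genes were high in some libraries of the starch diets and the Western diet. Defb1 exceeded the highest chow library (220.6) in 5 of the 16 starch-fed libraries. That limit rests on chow replicate 4: without it the highest chow value was 31.4, and 8 of the 16 exceeded it, so a response shared by the mice of a diet stays open. Within diets, Defb1 rose and fell with the mean of the other 5 list members over the 40 libraries on fat-rich diets (Spearman rho 0.580, Pearson r 0.821, permutation p = 3e-04 for the first, and 0.511 and 0.763 without the 2 most extreme libraries). This is consistent with epididymal tissue carried over in those libraries, a hypothesis, since the list was looked at on the same data. Western diet replicate 2, with 173666 counts of Clu and 1255.4 of Defb1, stayed below the limit of the list score (7.39 against 7.66), and its source remains open.

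Leukocyte genes were higher and adipocyte genes lower with starch/oleate, starch/palmitate and sucrose/oleate. For starch/oleate, a lower share of adipocytes alone would raise macrophage and endothelial genes alike, but the macrophage list rose by 1.23 ± 0.24 (SE, log2) more than the endothelial list, 5.07 standard errors. Carry-over of epididymis in the libraries set apart is argued against as the whole cause, since 311 genes were called without the 6 libraries. Lesser carry-over was not tested: starch/oleate replicate 4, which stayed in, had 265.5 counts of Defb1. With the positive control ratio as a covariate 273 genes were called, which argues only weakly against a run difference it tracks as the whole cause. The ratio ran from 3.11 to 3.28 on starch/oleate and from 3.17 to 3.39 on chow. Of the chow libraries only replicate 3 (3.17) lay within the starch/oleate range, so the covariate had little overlap to separate run and diet. The mean ratio was 3.20 on starch/oleate and 3.33 on chow, so a run difference that the ratio does not show stays open. For starch/palmitate (2 genes called with the ratio as a covariate) and sucrose/oleate (30) run and diet cannot be told apart. The differences of the genes called without it had a median size of 0.60, from 0.73, and 0.55, from 0.72, while the median SE rose to 0.29, from 0.22, and 0.28, from 0.19, so the calls ended with smaller differences and larger errors together. The adipocyte list kept its call in both (adjusted p = 0.00025 and 0.00023). The question stays open for all genes, the adipocyte list included, since no library of either group lay within the chow range of the ratio, nor a chow library in theirs. A change in the cells themselves or in their numbers may underlie the starch/oleate difference and was not tested.

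More genes rose than fell against chow. With TMM scaling the share of higher calls for starch/oleate moved to 57.7%, from 80.1%, and rises still outnumbered falls (164 against 120). TMM scaling sets most genes to no difference, so a more even share is built in. Whether scaling to the reference genes causes part of the imbalance therefore stays open. Background counts scaled up in some libraries are argued against, since with a mean count of at least 30 the share was 79.3%. Which scaling is closer to the RNA in the tissue stays open, as 9 of the 14 reference genes passed the test themselves.

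Samples far from the others of their group were found for 51 of 450 pairs of a group and a gene named in the text, where chance sets apart about 1 in 20, or 22.5. The named genes include the largest differences, which single extreme libraries can cause, so part of this excess may come from how the genes were picked. Western diet replicate 2 accounted for 12, low for Cd36 (18964), Itgax (1473), Cd14 (414), Trem2 (492), Lair1 (192), Cd22 (45.5), Blnk (751), Il1rl1 (93.8) and Tnfsf13b (39.8) and high for Kit (122), Clu (173666) and Tcf7 (1140). Chow replicate 4 accounted for 9, low for Itgax (169), Fcgr1 (78.7), Fcgr4 (27.4), Ly86 (258) and Il1rn (75.1) and high for Ptgs2 (330.2), Defb1 (220.6), Ceacam1 (303) and Gata3 (197). Sucrose/oleate replicate 2 accounted for 8, low for Itgax (2559) and high for Il1b (199), C3 (14026), Cxcl13 (5490.3), S100a9 (2051), Ccl12 (550), Cxcr2 (274) and Icam2 (453). Replicate 6 of that group was low for Gata3 (15.5) and high for Bcap31 (5302). In sucrose/palmitate, replicate 4 was high for Stat4 (1191), Cd59b (124) and Cd46 (131), replicate 3 for Ptgs2 (9674) and Gata3 (1063), and replicate 2 for Il22ra2 (87.3), while replicate 1 was low for Cd8a (3.97) and replicate 6 for Cd4 (18.2). In starch/palmitate, replicate 3 was high for H2-Q10 (8669) and Tlr5 (147) and replicate 7 for Il22ra2 (52.9), and replicate 1 was low for Cd4 (21.3). In starch/oleate, replicate 1 was high for Ccl2 (1907), replicate 6 was low for Cd22 (124) and Il12rb2 (34.5), and replicate 3 was low for Il1a (9.03). In chow, replicate 7 was high for Pax5 (28.9) and low for Irak2 (889), replicate 5 was high for Tigit (13.5) and replicate 8 low for Clu (1647).

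The interaction test found that the log2 difference of sucrose minus starch was larger with palmitate than with oleate for Cd79b (2.15), Ms4a1 (2.20), Pax5 (1.76), Tnfrsf13c (0.99), Tnfrsf17 (0.86), Tfrc (1.40), Il1a (1.83), Kit (1.03), Fcer1a (1.04), Marco (2.34) and Stat4 (2.12). It was smaller for Cd1d1 (-1.19), Bcap31 (-0.40), Cxcl9 (-1.82), H2-Q10 (-3.93) and Pigr (-4.40). The value of Stat4 rests on sucrose/palmitate replicate 4 (1191 counts against at most 61.4 in the others) and was -0.84 with the positive control ratio as a covariate. Starch/palmitate replicate 3 held 8669 counts of H2-Q10 and 8628.7 of Pigr. None of the 16 genes passed with the positive control ratio, which differs along the same contrast, so assay run and interaction were not told apart.

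Among the 56 genes with a mean count below 10, which the comparisons did not use, edgeR found 13 rises against chow in a fit without the filter (falls were not searched). As log2 differences they were Aire on sucrose/palmitate (1.33), Ccl26, Klra4 and Klrc3 on starch/palmitate (1.04, 0.87 and 1.30), Klrc3 on sucrose/oleate (1.14), Ccl26, Cr2, Il4 and Klra1 on starch/oleate (0.86, 1.25, 0.86 and 0.80), and Ccl26, Cr2, Il17f and Klrc3 on the Western diet (1.03, 1.10, 1.38 and 1.44). Group means of these genes lay between 1.63 and 21.7 counts, near the negative controls.

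For each count of changed genes, 100 groupings of the same samples were tried, the real one included. Only the real grouping reached its count (1 of 100) for starch/palmitate (128, highest other 82), sucrose/oleate (180, 107), starch/oleate (296, 168), the Western diet (201, 180), the carbohydrate effect (49, 12), the fat effect (172, 132), the interaction (27, 14), sucrose minus starch with oleate (74, 17) and palmitate minus oleate with starch (160, 92). For sucrose/palmitate 2 of 100 reached 84 (highest other 146), and for palmitate minus oleate with sucrose 2 reached 21 (22). Chance is excluded at 0.05 for these counts, except that of the interaction. Its groupings mixed samples across the custom diets, which removes the carbohydrate and fat effects as well. They test for no difference among these diets, so they cannot decide whether the interaction count came by chance. Chance is not excluded for sucrose minus starch with palmitate, where 9 reached 10 (highest other 164). Nor is it excluded for the Western diet against sucrose/palmitate, where 5 reached 31 (highest other 111). Other groupings with counts several times the real one can come from a structure of the samples or from single libraries with extreme values, and the cause was not tested.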

How the results depend on the processing

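Leaving out the 6 libraries or single libraries, the positive control ratio and its chow range were chosen after the data were seen. The count for any difference among the 6 groups stayed between 282 and 332 over the alternatives run for it. A count is called kept when within 1.5 times that reported. Counts against chow for starch/palmitate, sucrose/oleate, starch/oleate and the Western diet were kept under TMM scaling, both filters, the replicate block, only the compared groups, DESeq2 and without the 6 libraries, and so was that of the fat effect under all 9 alternatives. Of 319 gene results, 298 kept their side of the threshold with TMM scaling (18 lost it, 3 gained it) and 214 with the positive control ratio (101 lost it, 4 turned sign); of 80 list results 46 kept it with TMM scaling (27 lost it) and 37 with the lymph node list (41 lost it). The causes below were not tested, except that fewer samples or an added covariate widen the errors by construction. Alternatives for values already normalized (a pseudocount, rescaling to reference genes, robust moderation) were not run, since the table holds raw counts. Genes near the background of 7.51 counts limit what can be seen.

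Counts that moved were as follows. Lymph node list as a covariate: sucrose/palmitate 10, starch/oleate 186, interaction 6, sucrose minus starch with palmitate 16 and with oleate 36, palmitate minus oleate with starch 81 and with sucrose 77. Only the groups compared: sucrose/palmitate 14, sucrose minus starch with palmitate 0 (39 at an unadjusted p below 0.05 in edgeR) and with oleate 154, Western diet against sucrose/palmitate 16. Positive control ratio: sucrose/palmitate 40, starch/palmitate 2, sucrose/oleate 30, interaction 0 (78 unadjusted), sucrose minus starch with palmitate 1, palmitate minus oleate with sucrose 1. Sucrose/palmitate with its 2 libraries in the chow range of that ratio gave 13. Replicate block: carbohydrate effect 30, sucrose minus starch with palmitate 1, palmitate minus oleate with sucrose 3, Western diet against sucrose/palmitate 14. Without the 6 libraries: sucrose minus starch with palmitate 0 (40 unadjusted) and with oleate 114, palmitate minus oleate with sucrose 48, Western diet against sucrose/palmitate 81. Palmitate minus oleate with sucrose had 36 with TMM scaling and 36 with DESeq2.

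Without single libraries the counts ran from 25 to 118 for sucrose/palmitate, 87 to 161 for starch/palmitate, 157 to 195 for sucrose/oleate, 277 to 307 for starch/oleate, 160 to 225 for the Western diet, 24 to 61 for the carbohydrate effect, 149 to 197 for the fat effect, 19 to 37 for the interaction, 0 to 15 and 50 to 96 for sucrose minus starch with palmitate and with oleate, 122 to 192 and 3 to 30 for palmitate minus oleate with starch and with sucrose, and 14 to 58 for the Western diet against sucrose/palmitate. The 0 was without starch/palmitate replicate 3.

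Differences that turned sign were these. Lymph node list: Ms4a1 -0.00905 for sucrose/palmitate; Cxcl13 -0.81 for starch/oleate; the lymph node list itself -0.0374 for starch/oleate and -0.0101 for sucrose minus starch with oleate, since the covariate is its own mean. Without the 6 libraries: Ceacam1 -0.12 for starch/palmitate; Clu -0.48, Defb1 -1.21 and Tcf7 -0.0459 for the Western diet; Mme 0.36 for the carbohydrate effect; Clu -0.87 and C4bp -0.96 for the Western diet against sucrose/palmitate. DESeq2, which replaces outlying counts: Clu -0.46 and C4bp -0.008274 for the Western diet; Clu -0.85, C4bp -0.0287 and Stat4 0.29 against sucrose/palmitate; Stat4 -0.12 for sucrose minus starch with palmitate and -0.24 for palmitate minus oleate with sucrose. Positive control ratio: Stat4 -0.84 for the interaction, -0.10 for sucrose minus starch with palmitate and -0.40 for palmitate minus oleate with sucrose, where Ptgs2 was -0.18. TMM scaling: the toll-like receptors and NF-kappa B list -0.0108 for sucrose/palmitate and 0.0306 for starch/oleate (its median; the test turned down); the cell death and autophagy list 0.0583, -0.003653, -0.13, -0.23 and 0.12 for sucrose/palmitate, starch/palmitate, sucrose/oleate, starch/oleate and the Western diet, each with the test turned down.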

Other observations

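Some gene groups have not been described. Of the 8 CXC chemokines tested, 3 rose with starch/oleate and 0 fell (3 adjusted over the list alone; fry adjusted p = 0.0095); Cxcl10, an interferon-induced chemokine, rose by 1.69 ± 0.37 there. The list lost its call with TMM scaling (adjusted p = 0.15) and with the lymph node list as a covariate (0.84). Regulatory T cell and checkpoint genes rose with starch/palmitate, 3 of 11 (4 adjusted over the list alone, fry adjusted p = 0.040). With starch/oleate 5 rose and 1 fell (5 and 1 adjusted over the list alone, fry adjusted p = 0.0085). On starch/oleate, Pdcd1 was higher by 1.02 ± 0.34 and Tigit by 1.02 ± 0.31. The chow means of these 2 genes (10.9 and 8.01) lay near the negative controls there (7.48), so the sizes are uncertain. The starch/palmitate call of that list was lost with TMM scaling (0.080), a mean count of at least 30 (0.075), the replicate block (0.062), only the groups compared (0.17), the lymph node covariate (0.075), the positive control ratio (0.57) and without the 6 libraries (0.090). Its starch/oleate call was lost with TMM scaling (0.54), a mean count of at least 30 (median 0.0172, adjusted p = 0.18), the lymph node covariate (0.63) and the positive control ratio (0.052). MHC class I genes did not pass as a list in any diet against chow, with 1 of 7 higher and 1 lower on starch/oleate (1 and 1 adjusted over the list alone; adjusted p = 0.67). With TMM scaling the MHC class I list (adjusted p = 0.0020) and the complement list (adjusted p = 4.8e-05) were called down on starch/oleate.

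Ptgs2, which encodes cyclooxygenase 2, the inducible prostaglandin synthase, spread widely within groups. These libraries were picked after the values were seen, and no test was run on them. On starch/oleate, replicates 1 to 5 held 1009.9, 2575.4, 1420.9, 1319.5 and 1806.3 counts, and replicates 6 to 9 held 112.3, 21.1, 33.8 and 32.1. Counts of 5920 in starch/palmitate replicate 7 and 1686 in Western diet replicate 1 stood above the rest of their groups too. Gata3 was at 829.8 in starch/palmitate replicate 7, where Defb1 was at 192.6.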
